A study of Mus musculus with 4 samples.

How the data were processed

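Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 4 libraries from E14TG2a.4 cells, a feeder-independent mouse embryonic stem cell line grown with LIF. The group of 2 Jarid1b libraries was made with an antibody against Jarid1b, the product of Kdm5b. The remaining 2 libraries were made with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3), 1 from cells transduced with a lentivirus carrying a scrambled short hairpin RNA (shRNA) and 1 from cells transduced with a Jarid1b shRNA.

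The deposited files hold 1 row per aligned read, with chromosome, start, end and strand. Per the labels' protocols and the submitters' processing notes, tags were mapped to mm9 with Bowtie, whose version is not given in the sources used here. The same protocols describe keeping 1 match per position, calling peaks with MACS at an FDR below 0.2 and normalizing to IgG. The deposited rows still repeat positions, hold no peak and carry a score of 0, so they precede those steps. No IgG library and no list of peaks was used here. Chromosome lengths of the NCBIM37 assembly, which underlies mm9, hold the deposited coordinates, except for 5 read ends of the Jarid1b shRNA library that pass a chromosome end.

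The libraries held 5120111 rows (Jarid1b replicate 1, reads of 34 bases), 1736183 rows (Jarid1b replicate 2, 26 bases), 7530697 rows (scramble H3K4me3, 34 bases) and 2851928 rows (Jarid1b shRNA H3K4me3, 35 bases). On chromosomes 1 to 19, X and Y, 1 read was kept per chromosome, strand and 5′ position, which left 4336767, 1602370, 5158330 and 2635705 reads. Repeats made up 15.3%, 7.69%, 31.5% and 7.56% of the rows in the same order. The 5′ end of each read was shifted 75 bases towards the fragment centre.

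Promoters were windows of 1 kb on each side of the gene-level transcription start site (TSS) of 22367 protein-coding genes in the GENCODE vM1 annotation. Within each library, the reads of a window were compared by a one-sided Poisson test with the larger of the genome rate and the local rate in 10 kb on each side. The genome rate gave 3.39, 1.25, 4.03 and 2.06 reads per window in the 4 libraries in the order above. P-values were adjusted over all windows by the Benjamini-Hochberg method, with a threshold of 0.05. A promoter was called Jarid1b enriched when it passed in both Jarid1b libraries. These p-values cover counting error within 1 library and say nothing of the spread between cultures.

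The ratio of H3K4me3 between the knockdown and the scramble library was taken on reads scaled to the total of reads kept (RPM), over promoters enriched in either library with at least 20 reads over both. Its 95% interval is the exact Clopper-Pearson interval conditional on the summed reads. A promoter was called higher or lower when the ratio was at least 2-fold and its interval excluded 0 on the log2 scale. With 1 library per condition there was no replicate check and no test between conditions, and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of medians are order-statistic intervals over promoters, which are not replicates. Shares have Wilson intervals. For the overlap with H3K4me3, random promoters were also drawn within 100 classes of GC content, chosen after seeing the data. Groups of promoters were set against 10000 random lists of the same size, matched on H3K4me3 level as fixed in advance, and also on GC content or on both. Genome-wide, 1 kb bins were tested in the same way and adjacent enriched bins were merged into regions.

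Gene groups were 18 lists fixed before the data were examined: pluripotency regulators, Hox genes, regulators of mesoderm, endoderm and trophoblast, neural regulators, neuronal and glial genes, germ line genes, cell cycle inhibitors, cell cycle genes, housekeeping genes, ribosomal protein genes, oxidative phosphorylation genes, proteasome genes, H3K4 methylation regulators, Polycomb genes, imprinted genes, fibroblast genes, blood and liver genes, and tissue genes silent in stem cells. The rule for naming genes was fixed at the same time. It took Kdm5b, the 10 promoters with the highest mean Jarid1b enrichment, and the 8 highest and 8 lowest H3K4me3 ratios with at least 50 reads and an interval excluding 0. From each list it took the 3 members with the highest Jarid1b enrichment and the 2 with the largest H3K4me3 ratio in either direction. Any other gene is named as chosen after its values were seen. Symbols that belong to several genes were not named. Some genes that the rule selects are not reported here.

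Some adjustments were chosen after seeing the data, as was the matching of random lists on GC content. Reads in 1 kb background bins of the autosomes were averaged in 14 classes of GC content. These bins lay over 5 kb from any TSS and were not enriched in either H3K4me3 library. Bins with 30 or more reads in Jarid1b replicate 1 or the scramble library were left out. Bins next to enriched ones and other Jarid1b-enriched bins were kept. In one adjustment, the Jarid1b background of a promoter was raised to at least the rate of bins of its GC class. In the other, the trend of the knockdown over scramble ratio with GC in those bins was subtracted from the promoter ratios. All bins above 60% GC formed 1 class, so the adjustment is incomplete for the most GC-rich promoters. After the second adjustment the median promoter ratio still rose with GC content over the whole range. It went from 0.11 up to 45% GC to 0.53 at 60% to 65% and 0.91 above 65%. Values with the GC trend removed may therefore keep a part of that trend, which was not tested further. Minus-strand reads of both Jarid1b files lay 1 read length to the left of their place: 184 and 31 of them covered 3 or more uncalled bases as deposited, and 0 did after a move by 1 read length. Coordinates were used as deposited, and the move is 1 of the alternatives.

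The steps were tested on simulated data drawn from the measured backgrounds of the 22367 promoters. Of 100 promoters raised 3-fold, 5 were called enriched in both Jarid1b libraries, of 100 raised 6-fold 50 were, and 0 of the unraised promoters were. Reads that followed only the GC trend of background bins gave 227 calls without and 0 with the GC-adjusted background. That background holds the same GC trend that these reads were drawn from. The 0 therefore follows from the design and does not test how well the adjustment suits measured promoters. The simulated Jarid1b libraries were drawn without the fragments that the measured files share, so false calls in both libraries may be understated. For the H3K4me3 ratio, simulated over 13273 promoters, 97 of 100 promoters changed 3-fold and 100 of 100 changed 6-fold were called, beside 67 calls among the unchanged.

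Alternatives listed before the data were examined changed duplicate removal, the window, the threshold, the shift, the TSS, the background, the use of the Jarid1b libraries, the scaling, the depth, the minimum of reads and the chromosomes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, samtools 1.23.1 and, for plots, matplotlib 3.10.9.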

Results

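The study examined Jarid1b, a demethylase that removes methyl groups from lysine 4 of histone H3, and its substrate mark H3K4me3 in mouse embryonic stem cells. Its title asks about targets that regulate development and about neural differentiation. The data were 2 Jarid1b ChIP-seq libraries and 2 H3K4me3 libraries, 1 from cells with a scrambled shRNA and 1 from cells with a Jarid1b shRNA. Depth ranged from 1602370 reads kept in Jarid1b replicate 2 to 5158330 in the scramble H3K4me3 library. The median H3K4me3 promoter held 91 scramble and 62 knockdown reads, whereas the median Jarid1b-enriched promoter held 16 and 8 reads in the 2 Jarid1b libraries. Single Jarid1b promoters are therefore less precisely measured than H3K4me3 promoters. All coordinates are on mm9.

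The 2 Jarid1b samples were compared first, since their agreement sets how they can be counted. Over 12586 promoters with at least 10 reads they differed by less than the sampling noise, with a chi-square per degree of freedom of 0.896. Over 23993 windows of 100 kb it was 1.09, above that noise, against 6.28 for the scramble and knockdown H3K4me3 libraries. They also shared single fragments: 16.8% of the plus-strand positions of replicate 2 were at the same base in replicate 1, 9.52 times the median over other offsets. On the minus strand the share was 19.8%, at an offset of 8 bases, the difference between the 2 read lengths. The largest such excess among the tested pairs that included an H3K4me3 library was 1.18 times, on the plus strand. Offsets from −12 to 12 were scanned. Jarid1b minus-strand reads lay 1 read length to the left, so a minus-strand peak with an H3K4me3 library would have fallen outside that range. Given the shared fragments, the 2 Jarid1b files were counted as 1 sample (n = 1), and a call in both is not a check between cultures. Across 22350 promoters, which are not replicates, their counts had a Pearson r of 0.696 and a Spearman rho of 0.682. This leaves out 17 promoters with 100 or more reads, with which the Pearson r was 0.987.

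**Figure D1:**
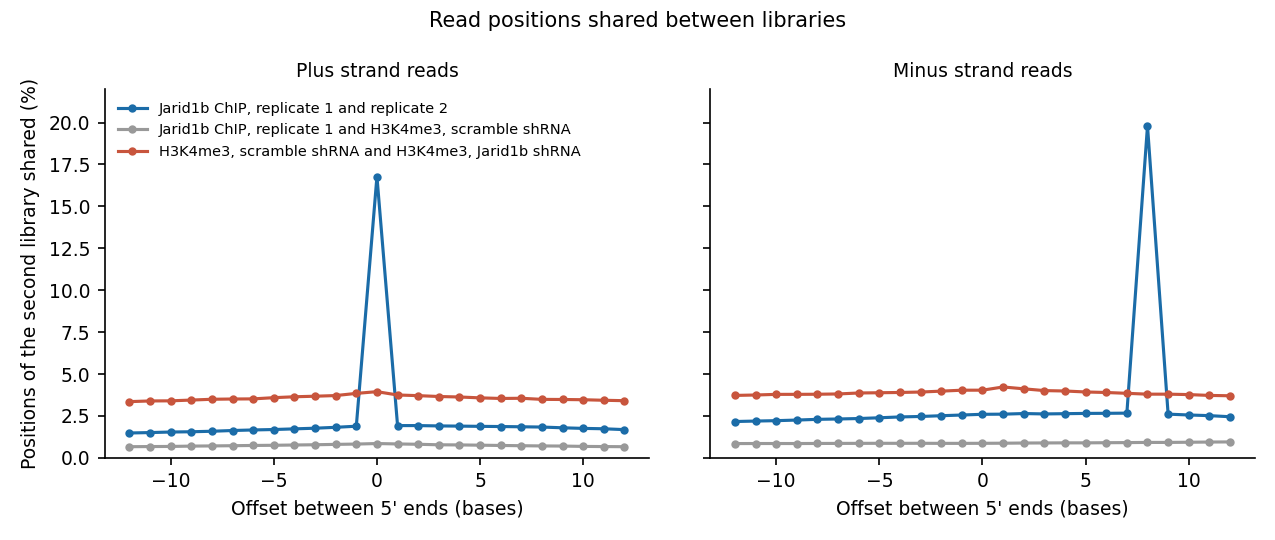
Percent of read positions of the second library found in the first, plotted against the offset between 5′ ends in bases, for plus-strand reads on the left and minus-strand reads on the right. The line of the Jarid1b pair peaks at 16.8% at offset 0 and at 19.8% at offset 8, while the other pairs have no such peak within the plotted offsets. For Jarid1b against H3K4me3 on the minus strand, these offsets could not have shown one.

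Jarid1b was enriched at 1783 of 22367 promoters, or 7.97%. Neural regulators were the list with the largest share, with 20 of 47 promoters enriched where lists of the same GC content hold 9.71 on average. Among them were Olig1 (a transcription factor of the oligodendrocyte lineage), with 8.11-fold enrichment in replicate 1 (95% Poisson interval 5.47 to 11.6) and 8.95-fold in replicate 2 (5.21 to 14.3), Bhlhe22 (6.19-fold and 6.43-fold) and Emx2 (4.33-fold and 6.82-fold), which patterns the cerebral cortex. Regulators of mesoderm, endoderm and trophoblast had 13 of 41 promoters enriched, against 5.46, including Isl1 (4.57-fold and 6.39-fold), Gata5 (3.59-fold and 6.96-fold) and Gsc (3.24-fold and 7.14-fold), the organizer gene goosecoid. Hox genes, which set position along the body axis, had 7 of 38 against 4.99 in lists of the same GC content, with Hoxc13 (2.86-fold and 5.62-fold) and Hoxd13 (3.20-fold and 4.86-fold) enriched and Hoxa4 (4.20-fold and 2.27-fold) short of the threshold in replicate 2.

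Genes of differentiated neurons and glia had 8 of 25 promoters enriched, against 2.46 in lists of the same GC content, among them Nefl (7.50-fold and 7.98-fold), a neurofilament subunit, Reln (5.31-fold and 9.58-fold) and Gad2 (8.05-fold and 3.50-fold), which makes the transmitter GABA. Pluripotency regulators had 4 of 29, against 3.32, including Sox2 (4.22-fold and 4.80-fold) and Pou5f1 (1.92-fold and 4.19-fold), both core factors of stem cell identity. Polycomb genes had 5 of 26, against 4.46, including Bmi1, Suz12 (3.25-fold and 7.19-fold) and Phc3 (3.43-fold and 6.39-fold). The H3K4 methylation regulators had 3 of 18, against 3.18, which were the methyltransferase genes Mll1 (5.45-fold and 4.00-fold), Mll2 (2.27-fold and 4.50-fold) and Mll3 (3.06-fold in replicate 1). Imprinted genes had 4 of 19, against 1.501, with Impact (3.83-fold and 6.15-fold) and Magel2 (2.65-fold and 4.79-fold) enriched. Fibroblast genes had 3 of 22, against 1.78, namely Twist1 (28 and 6 reads), Twist2 (26 and 10 reads) and Cdh11 (3.41-fold and 8.12-fold).

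Lists of genes active in most cells had counts near those of lists of the same GC content. Housekeeping genes had 1 of 26, against 2.39 (Pgk1, a glycolytic enzyme gene, 5.90-fold and 4.29-fold), oxidative phosphorylation genes 1 of 35, against 1.64 (Cox5a, 3.09-fold and 5.59-fold), and proteasome genes 2 of 30, against 1.23, with Psmd11 at 2.95-fold and 6.39-fold. Ribosomal protein genes had 3 of 45, against 2.93, including Rps29 (18 and 13 reads) and Rps27l (3.24-fold and 5.59-fold). Cell cycle genes had 2 of 32, against 2.92, the cyclin E genes Ccne1 (2.39-fold and 4.58-fold) and Ccne2 (5.53-fold and 5.59-fold). Cell cycle inhibitors had 2 of 13, against 1.80, with Cdkn2a (4.42-fold and 3.68-fold) enriched. Germ line genes had 1 of 26, against 1.11 (Sycp1, of the synaptonemal complex, 3.54-fold and 4.79-fold). None of the 21 blood and liver promoters and none of the 28 tissue promoters silent in stem cells were enriched. Kdm5b itself reached 2.97-fold in replicate 1 and 1.74-fold in replicate 2 (0.474 to 4.45) and was not called.

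The 10 promoters with the highest mean enrichment were those of Phf21a, Clcn4-2, Crebzf, Bmi1, Kcnk12, Taco1, C530025M09Rik, Cacna2d3, Gpr25 and Map3k5. Bmi1, a component of Polycomb repressive complex 1, had 26 and 19 reads between bases 18597645 and 18599644 of chromosome 2, or 6.50-fold (4.25 to 9.52) and 15.2-fold (9.13 to 23.7). Map3k5, a stress-activated kinase gene on chromosome 10, had 35 and 17 reads, or 7.95-fold and 10.6-fold. Phf21a, Taco1 and Crebzf differ from the rest in that 75.4%, 79.7% and 66.7% of their Jarid1b reads lay within 200 bases.

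GC content bounds how these counts can be read. Jarid1b reads in background bins went from 0.359 per kb at the lowest GC content to 6.38 per kb at the highest in replicate 1, and enriched promoters had a median GC content of 59.0% against 53.7% for the other scramble H3K4me3 promoters. With the GC-adjusted background, chosen after seeing the data, 103 promoters were called in both libraries, all of them among the 1783, and 1370 on the pooled reads, which count shared fragments in both files, against 7623 on the pooled reads without the adjustment. By list, the 103 held 10 neural regulators, 3 regulators of mesoderm, endoderm and trophoblast and 2 Hox genes. They also held 1 each of the Polycomb, imprinted and ribosomal protein genes. In lists of the same GC content the averages are 0.61, 0.24, 0.30, 0.20, 0.087 and 0.13, in that order. No other list kept a call, including the neuronal and glial genes and the pluripotency regulators. There the averages are 0.036 to 0.22, so a count of 0 says little. Of the 103, 8 had over 50% of their Jarid1b reads within 200 bases, among them the ribosomal protein gene Rps29 (51.6%). Several promoters of the 103, all of genes with Gm symbols, held between 1908 and 2987 Jarid1b reads over both libraries. Bmi1, also among the 103, held 45. Such promoters were not left out.

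The median enrichment of each list was also placed among random lists of the same GC content, chosen after seeing the data. It lay at the 99.57 percentile for proteasome genes, 97.87 for neural regulators, 97.86 for germ line genes, 97.0 for imprinted genes and 95.1 for oxidative phosphorylation genes. It lay at 84.35 for regulators of mesoderm, endoderm and trophoblast, 71.4 for neuronal and glial genes, 70.75 for cell cycle genes and 56.54 for cell cycle inhibitors. The lower percentiles were 34.45 for Polycomb genes, 26.475 for blood and liver genes, 26 for silent tissue genes, 23.525 for pluripotency regulators, 22.51 for fibroblast genes, 11.02 for Hox genes, 10.75 for H3K4 methylation regulators, 8.325 for ribosomal protein genes and 2.41 for housekeeping genes.

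Jarid1b ChIP enrichment overlapped H3K4me3. Of the 1783 Jarid1b-enriched promoters, 1740 were enriched for H3K4me3 in the scramble library, or 97.6% (95% Wilson interval 96.8 to 98.2), where independent lists of these sizes share 1070.5. Random promoters of the same GC content, a comparison chosen after seeing the data, carried H3K4me3 in 89.3% (88.1 to 90.5 in 95% of draws). Conversely, 12.96% (12.4 to 13.5) of the 13429 scramble H3K4me3 promoters were Jarid1b enriched. The median enrichment was 2.03-fold and 2.07-fold at scramble H3K4me3 promoters and 0.885-fold and 0.798-fold at promoters with H3K4me3 in neither library. In 10 equal groups of promoters ordered by H3K4me3 level, the group at 3.88 RPM had medians of 1.79-fold and 1.76-fold. In the 5 groups above it, medians in replicate 1 lay between 1.97-fold and 2.14-fold while median scramble H3K4me3 went from 8.53 to 41.5 RPM, and the share called enriched ranged from 9.70% to 16.7%. Relative to bins of the same GC content, the medians at H3K4me3 promoters were 1.28-fold and 1.24-fold, against 0.933-fold and 0.764-fold. Of the 103 promoters called with the GC-adjusted background, 95 carried scramble H3K4me3, where independent lists share 61.8.

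**Figure D2:**
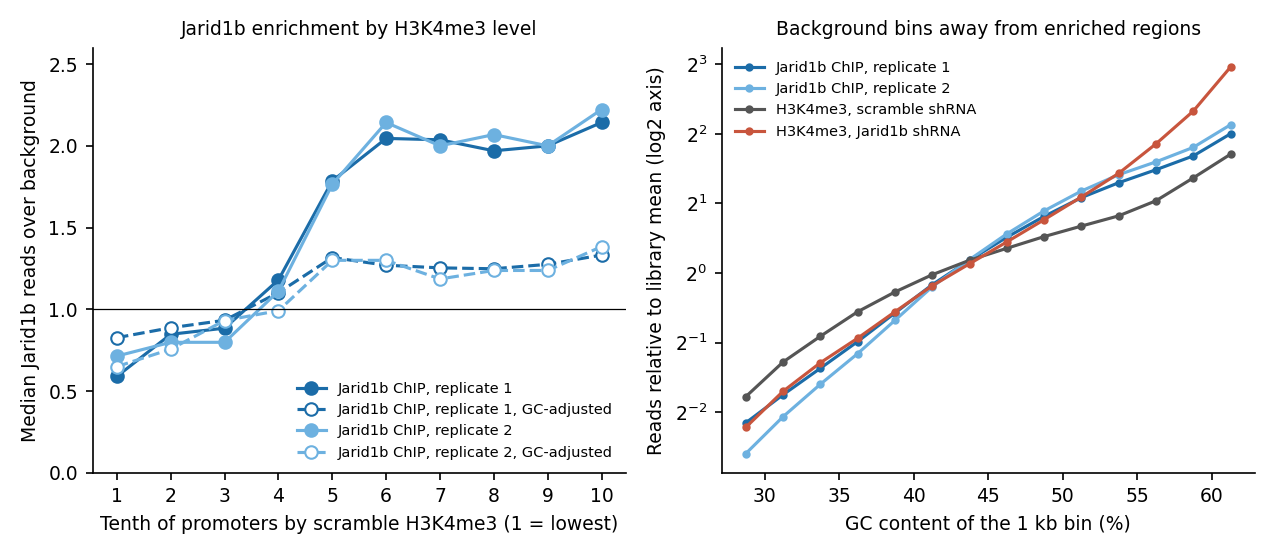
Left, median Jarid1b reads over background in 10 equal groups of promoters ordered by scramble H3K4me3, for both Jarid1b replicates, with filled points against the genome and local rate and open points against bins of the same GC content. Right, reads in background bins relative to the library mean against the GC content of the bin in percent, on a log2 axis, for the 4 libraries. Filled points stay between 1.97 and 2.22 in the upper 5 groups, and the knockdown H3K4me3 library rises most steeply with GC content, to 7.78 times its mean.

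Around the TSS, Jarid1b reads at enriched promoters peaked 275 bases downstream in replicate 1 and 225 bases downstream in replicate 2, at 5.69 and 7.92 times the flanking density. H3K4me3 peaked 175 bases downstream in both libraries. At Jarid1b-enriched promoters the H3K4me3 peak reached 37.7 times the flanks in the scramble and 74.7 times in the knockdown library. At the other H3K4me3 promoters it reached 35.1 and 50.9 times. Since the windows used for calling end 1 kb from the TSS, the shape of the Jarid1b profile at that distance is set in part by the calling.

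**Figure D3:**
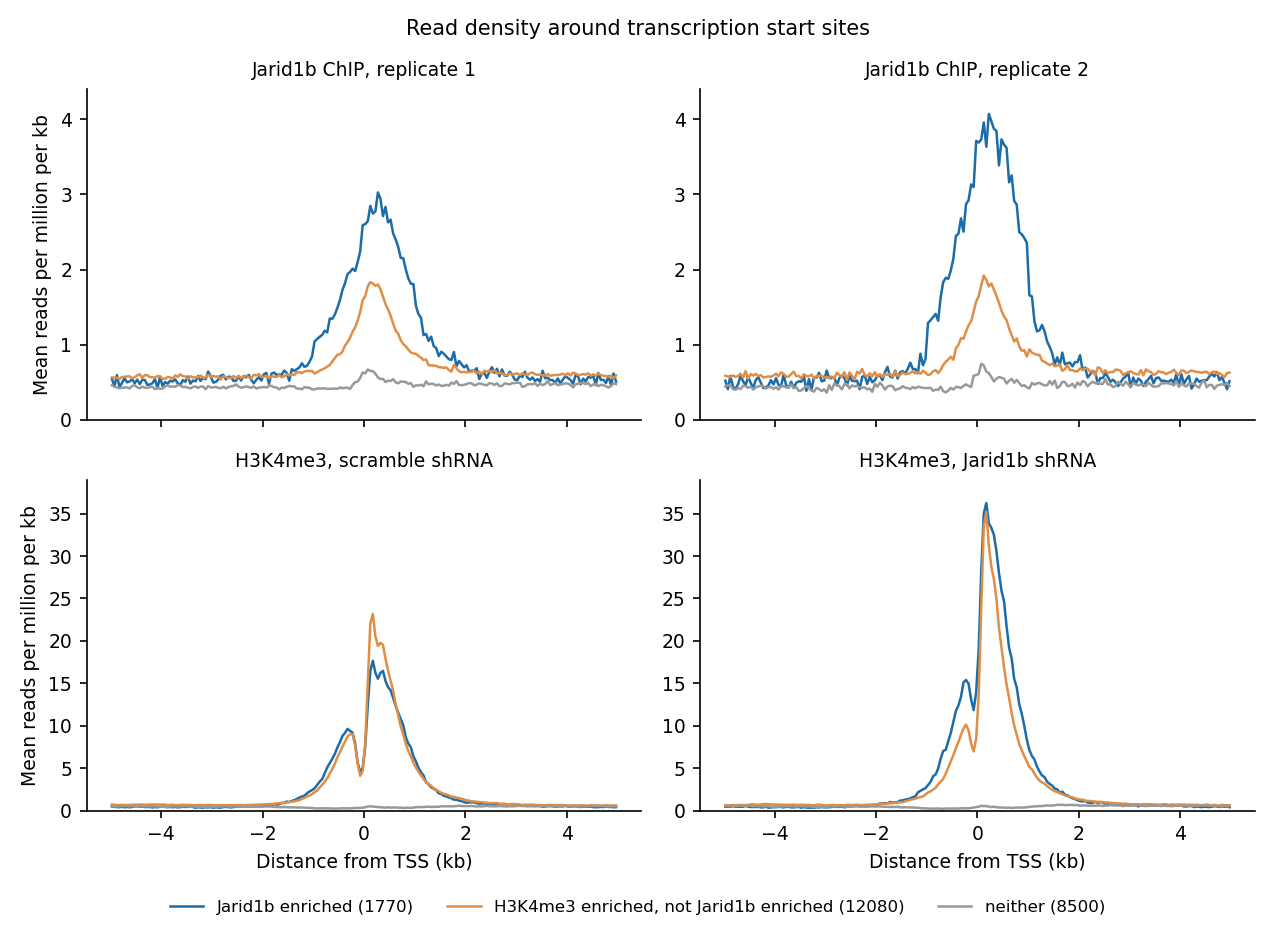
Mean RPM per kb in steps of 50 bases within 5 kb of the TSS, in the direction of transcription, for 1770 Jarid1b-enriched promoters, 12080 promoters with H3K4me3 only and 8500 with neither, 1 panel per library. The H3K4me3 peak of Jarid1b-enriched promoters stands at 17.7 in the scramble and 36.3 in the knockdown library.

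Genome-wide, 740 regions of 1 kb bins were enriched in both Jarid1b libraries, and 590 of them (79.7%) overlapped one of the 29711 scramble H3K4me3 regions by at least 1 base. A TSS lay within 1 kb of 30.9% of the 740 regions. This share was 13.1% at a threshold of 0.001 and 14.8% with bins of 500 bases, so most of the regions lay away from the TSS of protein-coding genes. The overlap of unrelated regions was not computed, so the 79.7% does not by itself show Jarid1b binding at H3K4me3 regions. The scramble H3K4me3 regions covered 43804 kb and held 38.3% of the reads of that library, and the 26318 knockdown regions covered 36698 kb and held 44.6%. Of the knockdown regions, 87.3% overlapped a scramble region.

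The effect of the Jarid1b shRNA on H3K4me3 was examined by comparing the knockdown and scramble libraries. The promoter of the targeted gene, Kdm5b, had 153 scramble and 155 knockdown reads, a log2 ratio of 0.99 (0.66 to 1.32). The shRNA acts on the transcript, so the H3K4me3 of this promoter does not check the knockdown. H3K4me3 was present at 13429 promoters in the scramble and 13399 in the knockdown library, with 12979 in common.

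Of 13273 promoters compared, 3184 were higher and 315 lower in the knockdown library, so that 91.0% of the called promoters were higher. The 8 highest ratios included Pou3f3, a neural POU factor, which went from 7 to 76 reads with a log2 ratio of 4.41 (3.30 to 5.77), Nfix (3.83), Ebf3 (3.48) and Prdm16 (3.46), all genes of transcription regulators, and the channel, receptor and membrane or synaptic genes Kcnd3 (3.72), Gabbr2 (3.67), Begain (3.59) and Vstm2b (3.45). The 8 lowest were Chd2, a chromatin remodeler gene (64 and 7 reads, log2 ratio −2.22, −3.60 to −1.10), Uty (−2.20) on chromosome Y, Gm14443 (−2.15), 2610001J05Rik (−2.09), Lefty1 (−2.08), an antagonist of Nodal signalling, Dkc1 (−2.04), Oasl1 (−1.95) and Rnf125 (−1.93). The difference has no replicate check. The median ratio of all promoters was 0.41 (0.38 to 0.43), and scaling the libraries to that median shifts every ratio by this amount and gives 1594 higher and 1193 lower promoters, 57.2% of them higher. Scaling to background bins gives 97.6%. The ratio also followed GC content across promoters (Spearman rho 0.628), and with the GC trend removed 2508 were higher and 66 lower. The 8 highest promoters had a GC content of 66.05% to 72.1%, and the 8 lowest of 39.65% to 55.2%. With the trend removed, the median ratio still rose from 0.11 at promoters up to 45% GC to 0.91 above 65%.

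Developmental lists stood above the median of all promoters. Of the 38 Hox promoters, 19 had enough H3K4me3 to be compared. All 19 had positive ratios and 14 were called higher, with a median log2 ratio of 2.06 (1.11 to 2.82). Hoxd9 stood at 3.14 (1.83 to 4.71), Hoxa11 at 3.06, Hoxd13 at 2.28, Hoxc13 at 2.19 and Hoxa4 at 2.06. Of the 38 neural regulators, 32 were called higher and none lower, with a median of 1.76 (1.41 to 2.21). Besides Pou3f3, Bhlhe22 had 2.34, Emx2 1.34 and Olig1 1.24, the last 2 of which were not called with median scaling (0.93 and 0.83) or with the GC trend removed (0.77 and 0.66). Of the 29 regulators of mesoderm, endoderm and trophoblast, 23 were called higher and none lower, with a median of 1.66 (1.25 to 2.09), and Msx1 (3.33) and Gsc (2.75) were among them. These medians lay at the 100, 99.86 and 99.99 percentile of random lists matched on H3K4me3 level and GC content, and they stayed above 1 under each scaling and with the GC trend removed. Of the 21 Hox promoters with H3K4me3 in either library, 15 had it in the scramble library. These counts were 32 of 40 for neural regulators and 24 of 33 for regulators of mesoderm, endoderm and trophoblast. The other promoters had it in the knockdown library alone, and including them favours positive ratios. Neuronal and glial genes had 9 of 17 called higher and a median of 1.15 (0.51 to 1.28), at the 90.9 percentile on level and GC content and the 98.8 on level alone, with Slc32a1 (2.17) and Nefm (1.65) the largest.

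Pluripotency regulators went the other way relative to the median of all promoters. Their 23 promoters had a median of −0.19 (−1.12 to 0.33), which turned to 0.06 with scaling to background, and 7 were called lower and 1 higher. Its percentile was 0.08 among lists matched on level and GC content and 0.13 on level alone. Lefty1 fell by 2.08, Pou5f1 had a ratio of −0.70 (401 and 126 reads), Sox2 0.23 (−0.08 to 0.53), which turned to −0.18 with median scaling and −0.34 with the GC trend removed, and Tbx3 was called higher at 1.44 (0.87 to 2.01). Ribosomal protein genes had a median of −0.53 (−0.69 to −0.34) over 44 promoters, at the 0.04 percentile, negative under each scaling and with the GC trend removed. Of these, 7 were called lower and none higher, with Rps28 at −1.61 and Rpl24 at −1.16, the second of which was not called with background scaling (−0.90) or the GC trend removed (−0.72). Housekeeping genes had a median of −0.33 (−0.55 to 0.31) over 22 promoters, at the 0.01 percentile, with Pgk1 (−1.23) and Tubb5 (−1.10) called lower and 1 promoter called higher. Neither lower call held with background scaling (−0.97 and −0.84) or with the GC trend removed (−0.97 and −0.66). Cell cycle genes had a median of −0.17 (−0.48 to 0.19), at the 2.54 percentile, and 0.09 with scaling to background, and of 32 promoters only Ccne2 (1.60) was called higher and only Brca1 (−1.01) lower, which did not hold with background scaling or with the GC trend removed (−0.75 in both).

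The other lists lay closer to the middle of lists matched on level and GC content, a matching chosen after seeing the data. Oxidative phosphorylation genes had a median of −0.18 (−0.40 to −0.13) over 35 promoters with no call, and proteasome genes −0.29 (−0.48 to −0.03) over 29 with 3 called lower, including Psmd8 (−1.10) and Psmb6 (−1.04), which were not called with background scaling (−0.84 and −0.78) or the GC trend removed (−0.84 and −0.60). Both medians turned positive with the GC trend removed, and the first also with scaling to background. Their percentiles were 33.7 and 33.99 on level and GC content, but 0.04 and 0 on level alone, the matching fixed in advance. Polycomb genes had a median of 0.75 (0.41 to 1.15) over 24 promoters at the 56.2 percentile, and the 96.3 on level alone, with 9 called higher, among them Bmi1 (2.80, 2.24 to 3.39), and 1 lower. H3K4 methylation regulators had a median of 0.49 at the 45.1 percentile, with 4 of 16 called higher, including Setd1b (1.65) and Mll2 (1.07), the second of which was not called with median scaling (0.66) or the GC trend removed (0.50). Cell cycle inhibitors had 0.48 at the 36.6 percentile, with 3 of 12 higher, including Cdkn2a (1.97) and Rb1 (1.75), and 1 lower. Imprinted genes had 0.70 at the 50.7 percentile, with Dlk1 (2.15) and Igf2r (1.56) the 2 called higher of 11. Germ line genes had 0.56 at the 85.9 percentile, with 3 of 12 higher, including Dazl (1.55) and Ddx4 (1.35), neither of which was called with median scaling (1.14, with an interval that then held 0, and 0.94), nor Dazl with the GC trend removed (0.98). Fibroblast genes had 1.01 at the 52.46 percentile, with 4 of 8 higher, including Twist1 (1.63) and Lox (1.59). On level alone the percentiles were 91.1 for fibroblast genes, 79.4 for H3K4 methylation regulators, 64.5 for imprinted genes, 62.7 for germ line genes, 60.1 for cell cycle inhibitors, 0.04 for cell cycle genes, 0.01 for housekeeping genes, 0 for ribosomal protein genes and 100 for the Hox, neural and mesoderm, endoderm and trophoblast lists. None of the blood and liver genes or of the silent tissue genes had enough H3K4me3 to be compared.

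**Figure D4:**
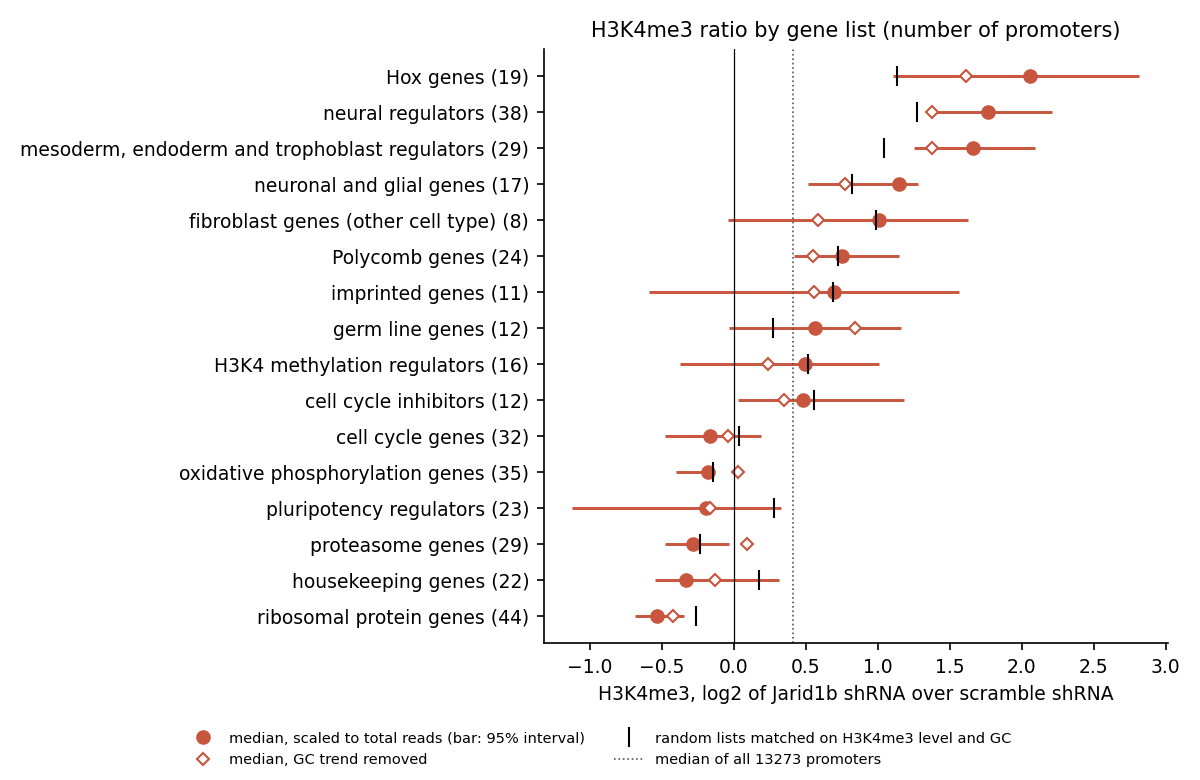
Median H3K4me3 log2 ratio of knockdown over scramble for the 16 gene lists with measured promoters, with 95% intervals over promoters as bars, the median with the GC trend removed as open diamonds, the median of matched random lists as ticks and the median of all 13273 promoters as a dotted line. Hox genes, neural regulators and regulators of mesoderm, endoderm and trophoblast have medians of 2.06, 1.76 and 1.66, and ribosomal protein genes have −0.53.

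The last comparison asked whether H3K4me3 differed between the libraries more where Jarid1b was enriched. The 1757 Jarid1b-enriched promoters had a median log2 ratio of 0.99, against 0.33 for the 11516 others, and 49.4% of them were called higher, against 20.1%. These shares were 30.6% and 9.18% with median scaling, 61.2% and 30.3% with background scaling, and 33.0% and 16.7% with the GC trend removed. On the pooled Jarid1b reads they were 32.4% and 14.1%, without replicate 2 34.5% and 16.1%, and without replicate 1 43.5% and 19.8%. Among those higher were Bmi1 (2.80), Map3k5 (2.52), Kcnk12 (2.08), Cacna2d3 (1.91) and Gpr25 (1.09), whereas Clcn4-2 (0.57), Crebzf (0.87) and Taco1 (0.03) were not called and Phf21a was called lower (−1.01). The call of Gpr25 ended with median scaling (0.68) and the GC trend removed (0.52), and that of Phf21a with background scaling (−0.75), the GC trend removed (−0.28) and all rows kept (−0.37). With all rows kept, Crebzf had 2.56. The share called lower was 0.398% for enriched and 2.67% for other promoters. The difference between the medians was 0.66 (bootstrap interval over promoters 0.62 to 0.72). The enriched promoters stood 0.60 above random lists matched on H3K4me3 level. They stood 0.11 above lists matched on level and GC content, whose medians ranged from 0.84 to 0.91 in 95% of draws. These lists were drawn from all compared promoters, enriched ones included, so both values understate the gap to the other promoters. Enriched and other promoters had medians of 0.86 and 0.62 at 55% to 60% GC, 1.28 and 1.01 at 60% to 65%, and 1.66 and 1.37 above 65%. Of the lower classes, only 45% to 50% had the reverse order (−0.34 and −0.24). The 99 measured promoters called with the GC-adjusted background had a median of 1.38, 0.35 above lists matched on both.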

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

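The thinning of the scramble library and the use of all rows were planned. The other tests of these patterns were chosen only after the results were seen, and the bounds of each test were set then.

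The call of 1783 promoters with Jarid1b was weighed against 3 other readings. GC-dependent recovery alone might produce it, but 97.6% of them carried scramble H3K4me3, against 88.1% to 90.5% of random promoters of the same GC content. This speaks against the GC content of the whole window as the only source. How GC content is spread within the window was not matched, so GC-dependent recovery is not excluded. Reads from repeated sequence might do so too, yet 66 of the 1783 enriched promoters had most of their reads from sequence that occurs again in the genome. Such sequence gave 27.2% of the plus-strand Jarid1b reads at the enriched promoters. The 103 promoters called with the GC-adjusted background were not tested apart in this way. More background from open promoters in any immunoprecipitation cannot be told apart from Jarid1b binding, since the GC-adjusted median of 1.28-fold at H3K4me3 promoters has no control library analysed here beside it.

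The higher H3K4me3 of the knockdown library at Jarid1b-enriched promoters was weighed in the same way. GC-dependent recovery that differs between the 2 libraries could account for much of the difference of 0.66, which was 0.30 with the GC trend removed. Whether it also accounts for the excess of 0.11 over lists matched on level and GC content, which could themselves hold enriched promoters, cannot be told. That matching used 20 classes of GC content, and GC content still varies within a class. Different depth could not be tested by thinning the scramble library, which left the difference at 0.66. Reads were dropped at random after duplicate removal, which leaves the expected ratios unchanged. With all rows kept in place of duplicate removal the difference was 0.71, so it did not rest on that removal. Less Jarid1b at these promoters could leave the excess of 0.35 at promoters called with the GC-adjusted background, but with 1 library per condition it cannot be told apart from a difference between cultures.

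In the scramble H3K4me3 library alone, the 100 kb window from base 2800001 of chromosome Y held 415.6 RPM and that from base 120700001 of chromosome X held 109.5. Reads from sequence in several copies might explain them, but 22.7% of the scramble reads of the Y window were multi-copy, against 27.9% library-wide, while 84.0% were in the X window, where the shares of the other libraries were no lower (94.9%, 90% and 96%) but rest on few reads, so that this reading cannot be told apart from others. H3K4me3 at promoters is unlikely for Y, since 92.7% of the 1 kb bins of the stretch held 10 or more reads. More copies of the stretch in the DNA behind the scramble library, from the cells or from foreign DNA, may be the source but cannot be told apart from others, since the 5 fullest of 55 bins held 23.8% of the reads, against 11.6% under even coverage.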

How the results depend on the processing

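Alternatives that adjust for GC content, move minus-strand reads or leave out piled promoters, and all of those for lists and single genes, were chosen only after the results were seen. The count of 1783 Jarid1b promoters went to 317 at a threshold of 0.001, 4132 at 0.2, 5539 with the genome rate, 7623 on pooled reads, 103 with the GC-adjusted background and between 2401 and 5991 without 1 replicate. Their overlap with H3K4me3, 97.6%, was 96.1% with 2 kb windows, 94.95% at 0.001, 94.5% with the genome rate, 96.6% at 0.2, 93.7% on pooled reads, 92.2% with the GC-adjusted background, 91.6% with both of the last, and 94.5% to 96.0% without 1 replicate. Higher promoters went from 3184 to 1594 with median scaling. Lower promoters went from 315 to 112 with background scaling, 1193 with median scaling and 66 with the GC trend removed. The difference of 0.66 at Jarid1b-enriched promoters was 0.89 at 0.001, 0.48 on pooled reads, 0.46 to 0.55 without 1 replicate, 0.98 with the GC-adjusted background, 0.30 with the GC trend removed and 0.77 with both. Shared regions went from 590 to 353 at 0.001. The sign turned for oxidative phosphorylation genes (0.077 with background scaling, 0.030 with the GC trend removed) and, with the GC trend removed, for proteasome genes (0.093), Ndufb3 (0.037), Psma1 (0.010) and Impact (0.00069). Where the interval of the main value already held 0, signs turned, among others, for pluripotency regulators (0.064) and cell cycle genes (0.093) with background scaling, for Sox2 (−0.34), Suz12 (−0.31) and Rps29 (0.093) with the GC trend removed, and for Sox2 (−0.18), Suz12 (−0.15) and Taco1 (−0.38) with median scaling. They also turned for Kdm5a (0.024), Psmb4 (0.17) and Uqcrc2 (0.21) with background scaling and for Tfrc (−0.099) and Stk31 (−0.026) with median scaling. The cause of these shifts was not tested. No paired analysis was possible because each H3K4me3 condition had 1 library.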

Other observations

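These observations and the genes named in them were chosen only after the results were seen.

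Beside Lefty1, the promoters of Nanog and Zfp42 had less H3K4me3 in the knockdown library, while the pluripotency regulators as a list were mixed. Of their 23 promoters, 7 were called lower and 1 higher, and 9 had positive ratios. Nanog, a core pluripotency factor, went from 239 to 52 reads with a log2 ratio of −1.23 (−1.69 to −0.79). Zfp42 went from 116 to 22 reads (−1.43, −2.16 to −0.76). With the GC trend removed the ratios of Nanog and Zfp42 were −0.64 and −0.70, short of 2-fold, so neither was then called lower. Scaling to background raises every ratio by 0.26, which also ends the call of Nanog but not that of Zfp42.

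Neural regulators made up 10 of the 103 promoters called with the GC-adjusted background, where lists of the same GC content hold 0.61 on average. Olig1 (2.86-fold over bins of the same GC content as the mean of both libraries) and Emx2 (2.62-fold) were among them. No neuronal and glial gene and no pluripotency regulator was among the 103, but lists of their GC content hold 0.093 and 0.21 on average. These counts of 0 therefore set neither list apart.

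On chromosome Y, the promoters of Eif2s3y (42 and 5 reads, log2 ratio −2.10) and Uty (45 and 5 reads, −2.20) were lower in the knockdown library, as was Ddx3y (18 and 3 reads, −1.62) with an interval that held 0 (−4.02 to 0.16), while the first 1200000 bases of Y, which hold them, had 1.54 times as many scramble as knockdown RPM. Chromosome X, outside its own stretch high in the scramble library, had 1.30 times as many, so much of the 1.54 is not particular to Y. The stretch from base 2847388 to base 2902555 held 2232 scramble and 19 knockdown reads.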
